A study of Zea mays and Oryza sativa with 119 samples.

How the data were processed

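Polyadenylated RNA was extracted with TRIzol from leaf sections and sequenced with a strand-specific library protocol, per the labels' protocols. The authors deposited 1 table of FPKM values (fragments normalized for transcript length and for the mapped fragments of the library) for maize and 1 for rice. Per the submitters' processing notes, TopHat2 2.0.10 and Cuffdiff 2.1.1 were used and the maize build was B73 RefGen_v3. The rice build, and how reads shared between similar genes were divided, are not given in the sources used here. Values of genes with near-identical copies are therefore uncertain, among them carbonic anhydrases, histones, light-harvesting proteins, tubulins, rbcS, and C4ppdkZm1 with CYPPDKZM2. The design text names 6 maize replicates, and 1 of them was not analysed here. Every value column of both tables was mapped to a labelled sample, with 0 left over.

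The maize table held 110005 features, of which 61077 were at 0 in every library, and the rice table had 55986, of which 22114 were. Gene names for maize came from a reference table of the Zm-B73-REFERENCE-NAM-5.0 assembly, used for names only. It gave an entry for 18915 features. Of the 23055 tested maize genes 13024 had an entry and 1815 a symbol. No table paired rice identifiers with names, so rice genes are given as the lists name them, and at most 2 identifiers that rose and 2 that fell are printed per comparison, which limits the rule for named genes in rice.

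Tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on all libraries of a species. Fold changes are on that scale and understate the change of genes with low values. Genes with a mean FPKM of at least 1 were tested. A gene was called changed between 2 sections at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1, and called different among sections by the F-test at the same adjusted p with a range of section means of at least 1. The comparisons were maize section 9 against 1 and 16 against 9, and rice section 6 against 1 and 11 against 6. Each gene list with 3 or more tested members was tested with camera, two-sided, at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a comparison. The tables of the 2 species were normalized separately and were not compared by a test. As each replicate is a pool of plants, p-values measure the spread between pooled replicates.

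The comparisons, tests, thresholds, list themes, rice list members and the rule for named genes were fixed before the data were examined. That rule takes every tested member of the C4, regulator and KNOX lists, then for each called list the 3 members that changed most and the 1 with the highest mean. It also takes the 5 named maize genes that rose most and the 5 that fell most among those with a mean FPKM of at least 5 and the same direction in every replicate. The patterns set for maize list members matched no symbol of the reference table, so members without a fixed identifier were chosen by symbol after the identifiers were seen and before expression was compared. Plastid and cytosolic ribosomal proteins were merged into 1 list. The maize lists were C4 cycle, bundle-sheath-preferred and mesophyll-preferred genes, which share members, Calvin-Benson cycle, light-harvesting proteins, photosystem subunits, GLK, SCR and SHR regulators, KNOX genes, DNA replication, mitosis, histones, ribosomal proteins, primary wall, secondary wall and lignin, wall loosening, epidermal wax, sucrose and starch, clock, chlorophyll breakdown, and stress and wounding. The rice lists included photorespiration and chlorophyll synthesis. The result of 1 gene in maize section 16 against 9 is not reported here. Lists added after the data were seen are reported with the other observations and adjusted separately.

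Relative depth was read from genes with a low mean, whose values step in whole fragments. For each library the most common distance of these genes to their lowest value was set against the median of the species, and libraries below 0.1 were called shallow. Of the tested maize genes, 22725 kept a mean FPKM of at least 1 without the shallow libraries. Position along the leaf was the centre of mass of a list's mean log2 profile in each replicate, in percent of the series of sections. Distance between neighbouring sections was 1 minus Pearson r across genes, which are not independent replicates.

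Replicate numbers come from the labels and mark samples of the same pooled plants. Deviations from section means had a median correlation of 0.0151 between maize libraries with the same number and -0.00415 between others, and in rice of 0.108 and -0.0371.

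The tests were checked on simulated data in which 100 genes were changed at each size. At a log2 change of 1.5 the share recovered was 43% in maize section 9 against 1, 41% in 16 against 9, 68% in rice section 6 against 1 and 61% in 11 against 6. At a change of 3 these shares were 90%, 90%, 96% and 90%. The simulated data held no other differences between sections, drew each gene independently and had no exact zeros, unlike the libraries. These shares therefore do not give the sensitivity of the real comparisons. Alternatives were another pseudocount (0.1), no filter or a mean of at least 5, quantile normalization, upper quartile scaling, a replicate block, no trend, only the 2 sections compared, and each replicate left out. Fits without the shallow libraries, section 7, the libraries out of place, maize section 16 replicate 6, or sections 9 to 11 of rice replicate 2 were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.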

Results

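Polyadenylated RNA was sequenced from consecutive pieces of the third leaf of maize, a grass with C4 photosynthesis, and of rice, a grass without it. The series title names the differentiation of C4 photosynthesis, studied through both leaf transcriptomes, as the question. The maize leaves came from 9-day seedlings of the inbred line B73. They were divided into 15 sections of 1 cm, which the labels number 1 to 4 and 6 to 16. Each maize section had 5 replicates, numbered 1, 2, 3, 4 and 6, and each replicate pooled 7 plants on average. The rice leaves came from 14-day seedlings of the cultivar Nipponbare and gave 11 sections of 2 cm, with 4 replicates that pooled 15 plants on average. The labels do not say whether section 1 is the base or the tip of the leaf. Expression was given as FPKM, fragments normalized for transcript length and for the mapped fragments of the library, in 75 maize and 44 rice libraries.

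FPKM holds no read totals, so the depth of each library relative to the median of its species was read from the steps between low values. Relative depth ran from 0.0034 to 2 in maize and from 0.66 to 1.52 in rice. Below 0.1 lay 6 maize libraries, called shallow from here on. Section 1 replicate 2 and section 3 replicate 6 each stood at 0.0625. In section 7, replicates 2, 3, 4 and 6 stood at 0.0034, 0.00897, 0.00781 and 0.0313. Section 16 replicate 6 was the next lowest of all maize libraries by this measure, at 0.109. Its FPKM ran high, as given below, which widens the steps, so its depth may be read too low. It listed 27.5% of the tested genes at 0, against 29.3% in section 16 replicate 2, which stood at 0.218. Relative depth in section 9 was between 0.287 and 0.871. Of the tested maize genes, a median of 12.3% were listed at 0 per library, with a range from 6.19% to 90.9%. In rice the median was 10.7% and the range 5.69% to 14.8%. The FPKM of a library summed to between 610337 and 1689980 in maize and between 462278 and 1187130 in rice. Section 16 replicate 6 held the highest maize sum. Over the tested genes it summed to 1682010, against 898500 to 934529 in the other 4 libraries of its section, and its median ratio to them was 2.05 over 16430 genes.

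**Figure D1:**
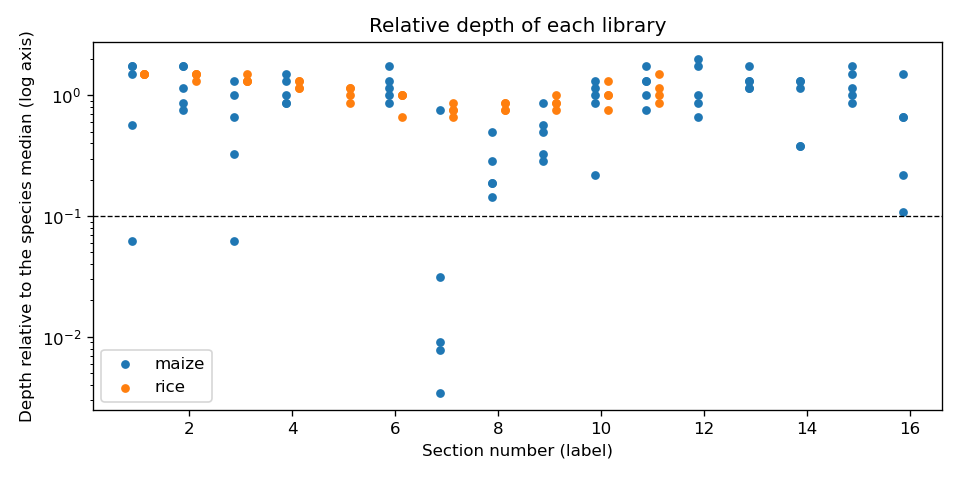
Relative depth of each library (log axis, 1 is the median of the species) against the section number in the labels, with 1 point per library. The dashed line marks 0.1, and the 6 points under it are maize libraries of sections 1, 3 and 7.

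Each library was set against the mean profile of every section, made from the libraries with other replicate numbers and without the shallow ones. In maize, 47 of the 75 libraries matched their own section best, 20 a neighbouring section and 6 a section at least 3 steps away. Leaving aside the shallow libraries, the last group held section 12 replicate 4, section 14 replicate 2 and section 16 replicate 3, called out of place from here on. These matched sections 9, 4 and 12. In rice, 31 of 44 libraries matched their own section and 12 a neighbour, and none lay 3 or more steps away. Sections 2 to 7 of rice replicate 1 each matched the next section, whereas its sections 1 and 8 to 11 matched their own. Section 6 of that replicate, used in both rice comparisons, had r at 0.928 with section 7 against 0.921 with its own. Maize section 7 had no profile for the libraries of replicate 1, so that section 7 replicate 1, counted among the 20, could not match its own section.

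Along the maize leaf, genes of cell division and protein synthesis were highest in the first sections and genes of C4 photosynthesis in the later ones. The mean of the tested DNA replication genes on the log2(FPKM + 1) scale was 3.83 ± 0.08 in section 1 (SD, n = 4 without the shallow library) and 0.95 ± 0.42 in section 9 (n = 5). Ribosomal protein genes averaged 7.09 ± 0.02 in section 1, 4.49 ± 0.34 in section 9 and 4.29 ± 0.58 in section 16. C4 cycle genes averaged 5.05 ± 0.24, 8.87 ± 0.09 and 8.98 ± 0.47 in the same sections. Genes of secondary walls and lignin, the polymer of woody walls, had their highest mean in section 3, at 6.91 ± 0.10, and stood at 3.53 ± 0.14 in section 9. Light-harvesting genes, whose products bind chlorophyll a and b, reached their highest mean in section 6, at 11.16 ± 0.10.

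The centre of mass of each list was taken in percent of the series of sections. It lay at 29.7 ± 4.4% for secondary wall and lignin genes, 30.7 ± 6.9% for ribosomal protein genes and 32.0 ± 5.5% for DNA replication genes (SD, n = 5 replicates). Light-harvesting genes lay at 53.6 ± 0.96%, photosystem subunits at 56.6 ± 0.95% and Calvin-Benson cycle genes at 58.5 ± 0.98%. The C4 list lay at 58.4 ± 1.2%, its mesophyll-preferred members at 57.2 ± 1.1% and the bundle-sheath-preferred members at 58.8 ± 1.6%. The order of the lists and the difference between the earliest and the latest, 29.1 points, rested on the measure. The crossing of the middle of the range lay at 12.9 ± 3.2% for light-harvesting, 15.7 ± 6.0% for Calvin-Benson and 17.1 ± 6.4% for C4 genes. Ribosomal protein and secondary wall genes both lay at 41.4 ± 24.9%. Both stood at 85.7% in replicate 2, the place of its section 14 library, called out of place. In lists that ended higher than they began, the crossing is the first section at or above the middle, and in others the last. It thus marks the start of a rise or the end of a high stretch, and gives no order between rising and falling lists. The difference between the earliest and the latest was 75.7 points by this measure. On linear FPKM secondary wall genes (33.5 ± 11.4%) lay after DNA replication genes (20.0 ± 4.2%), and the difference was 51.4 points. All these positions include the shallow and the out of place libraries. In replicate 2 the centre of mass of ribosomal protein genes lay at 41.6%, against 23.2 to 32.5% in the other replicates. Without the shallow libraries the centre of mass lay at 61.1 ± 2.0% for the C4 list and 61.5 ± 2.1% for Calvin-Benson genes. Photosystem subunits then lay at 59.2 ± 1.7%, mesophyll-preferred members at 59.6 ± 1.5% and bundle-sheath-preferred members at 61.6 ± 2.5%. Leaving them out removed section 7 from replicates 2, 3, 4 and 6, section 1 from replicate 2 and section 3 from replicate 6. Each profile was rescaled over the sections left. The C4 list stayed at 58.3% in replicate 1, which lost no section, and went from 59.3 to 64.0% in replicate 2. The shift thus cannot be told apart from the loss of sections.

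Of the 23055 maize genes tested, 19049 differed among the 15 sections (limma F-test). Among these, the highest section mean fell in section 1 for 6482 genes (34.0%), in section 4 for 3004 (15.8%) and in section 16 for 2563 (13.5%). Without section 16 replicate 6, whose values ran high, the count in section 16 was 1543 (8.10%). The section means behind these counts include the shallow libraries, which listed 38.8 to 90.9% of the tested genes at 0. The counts of sections 1, 3 and 7 may therefore be low. They were 865 in section 3 and 105 in section 7. Neighbouring sections were farthest apart between sections 6 and 7, with 1 minus Pearson r across genes at 0.390 ± 0.172 (SD, n = 5). That step held 4 shallow libraries and was 0.113 in replicate 1, the remaining one. Without the shallow libraries the largest step ran from section 8 to section 9, at 0.168 ± 0.030 (n = 5). The step from section 1 to 2 was 0.158 ± 0.051 (n = 4). Relative depth in section 8 was between 0.144 and 0.5. In replicate 1, the deepest there, the step from 8 to 9 was 0.119, below 0.143 from 1 to 2. The ranking of these steps thus lies within the spread and cannot be told apart from an effect of low depth.

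**Figure D2:**
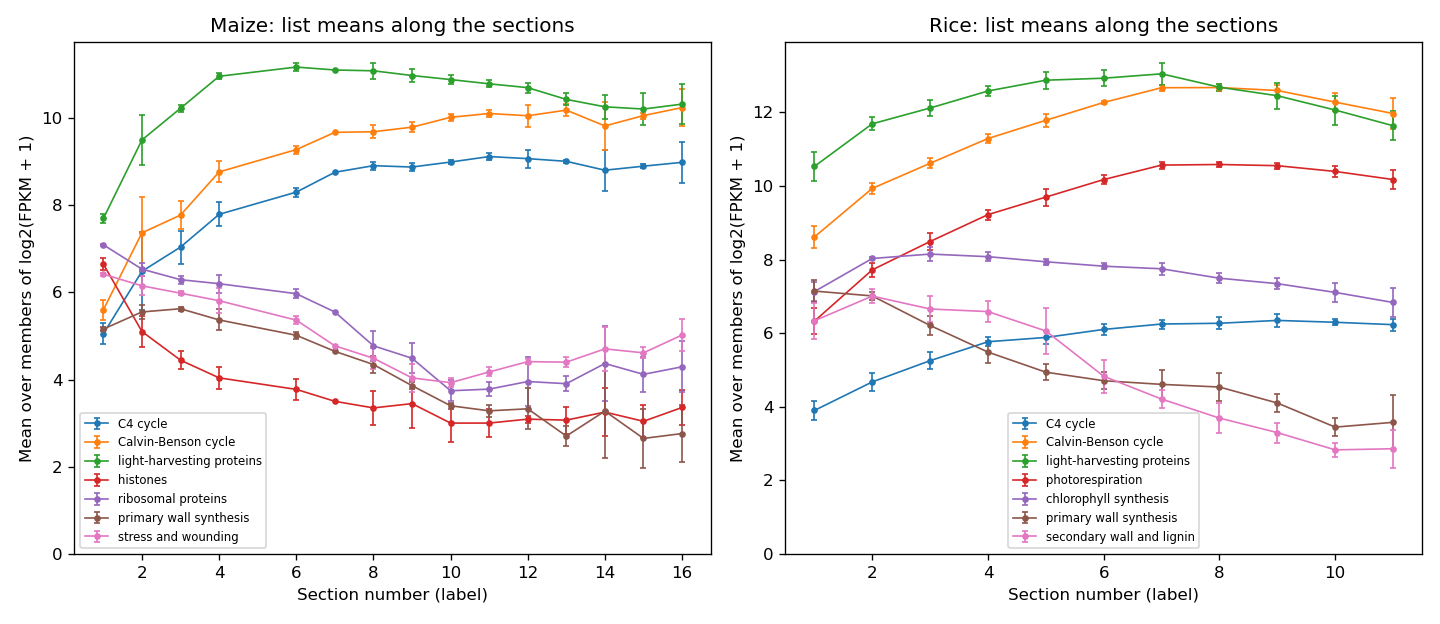
Mean log2(FPKM + 1) of the tested members of gene lists against section number in maize and rice, with bars for the SD over replicates and the shallow maize libraries left out, so that maize section 7 rests on 1 library. C4 cycle genes stand at 5.05 in maize section 1 and 8.87 in section 9, and ribosomal protein genes at 7.09 and 4.49. The levels of the 2 species were normalized separately and are not comparable.

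C4 cycle genes rose steeply from section 1 to section 9 of the maize leaf. The transcript of pep1 (GRMZM2G083841), the PEP carboxylase that fixes bicarbonate in mesophyll cells, went from 46.1 ± 13.8 to 2108 ± 146 FPKM (SD, n = 5 in each section), a log2 change of 5.53 ± 0.29 (SE, limma adjusted p = 3.03e-25). ME1 (GRMZM2G085019), the NADP-malic enzyme that releases carbon dioxide in bundle-sheath cells, went from 35.8 ± 16.2 to 2833 ± 209 FPKM and rose by 6.35 ± 0.38. C4ppdkZm1 (GRMZM2G306345), the dikinase that regenerates PEP, rose from 250.2 ± 74.7 to 15206 ± 913 FPKM. Over the same distance H4C13 (GRMZM2G084195), in the histone list, fell from 1723 ± 376 to 26.2 ± 45.3 FPKM, a log2 change of -7.58 ± 1.08 (adjusted p = 1.55e-08). Its section 9 mean is raised by replicate 1, at 107 FPKM against 0.773 to 13.4 in the other libraries.

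Of the 17 tested members of the C4 list, 15 rose and 1 fell. The median log2 change was 4.22, which is 4.76 above the median of all genes, and the camera adjusted p was 2.08e-20. Besides those above, the members that rose were 3 genes listed as carbonic anhydrase (GRMZM2G121878 by 6.30, GRMZM2G348512 by 5.98 and GRMZM2G094165 by 4.77) and GRMZM2G001696, listed as PEP carboxykinase, by 6.01 ± 0.79. The malate dehydrogenase mdh6 (GRMZM2G129513) rose by 3.60. Transporters of the chloroplast envelope rose as well. GRMZM2G138258, listed as MEP3, rose by 5.68, GRMZM2G070605, listed as a triose phosphate translocator, by 4.22, and pDCT2 (GRMZM2G086258) by 3.27. Smaller rises were 2.41 in pOMT1 (GRMZM2G383088), 2.40 in GRMZM2G174107, listed as a PEP translocator, and 1.51 in pDCT1 (GRMZM2G040933). The call of pDCT1 was lost with a pseudocount of 0.1 (adjusted p = 0.0612). The gene alt (GRMZM2G088064), listed as alanine aminotransferase, rose by 3.96. Its 5 section 1 libraries read 0.319, 0, 0.370, 0.262 and 0 FPKM, and those of section 9 from 14.7 to 20.2. GRMZM2G146677, listed as aspartate aminotransferase, fell by 1.30, but by 0.60 after quantile normalization and 0.62 after upper quartile scaling, which ended its call. GRMZM2G094712, listed under the same name, changed by -0.92 ± 0.64 and did not pass (adjusted p = 0.225).

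The other photosynthesis lists rose with it. All 6 Calvin-Benson cycle members rose, with a median of 3.96 (4.50 above all genes, adjusted p = 2.46e-12). GRMZM2G162529, listed as phosphoribulokinase, rose by 5.79, the Rubisco activase RA (GRMZM2G162200) from 114.3 to 1990 FPKM and the Rubisco small subunit rbcS (GRMZM2G113033) from 436.9 ± 59.4 to 6065 ± 356 FPKM. The activase gene rca3 (GRMZM2G162282) rose by 5.30, with 1.58, 0, 0.960, 1.31 and 2.24 FPKM in section 1 and 69.4 to 99.3 in section 9. All 7 light-harvesting members rose (median 2.83, adjusted p = 1.18e-11), led by cab48 (GRMZM2G120619), which went from 13.2 ± 4.2 to 985 ± 156 FPKM. In the same list cab-m1 (GRMZM2G351977) rose by 4.01, lhcb4 (GRMZM2G103101) by 3.53 and Cab-m7 (GRMZM2G402936) by 1.80. All 6 photosystem members rose (median 3.30, adjusted p = 9.49e-12), among them psad1 (GRMZM2G024150) by 3.80, psaN (GRMZM2G080107) by 3.37, psaH (GRMZM2G451224) by 3.36 and psa6 (GRMZM2G012397) by 3.25, all subunits of photosystem I. All 6 bundle-sheath-preferred members (adjusted p = 3.10e-11) and all 5 mesophyll-preferred members (1.18e-11) rose. These lists share genes with the C4 and Calvin-Benson lists. The calls of these 6 lists held with an estimated correlation, at adjusted p = 0.00389 for 5 of them and 0.00518 for the light-harvesting list.

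The DNA replication, histone, ribosomal protein and stress lists held mostly members that fell. Of 5 tested DNA replication genes 4 fell, with a median of -2.75, or -2.21 against all genes (adjusted p = 0.0106, and adjusted p = 0.0346 with an estimated correlation). RNRS3 (GRMZM2G323679), a ribonucleotide reductase subunit, read from 33.8 to 46.3 FPKM in section 1 and 3.57, 0, 1.11, 0 and 0 in section 9. The sliding clamp genes pcna2 (GRMZM2G108712) and PCNA (GRMZM2G030523) fell by 4.06 and 2.75. The section 9 libraries read 2.05, 0, 0, 0 and 0.940 for pcna2, against 17.8 to 27.9 in section 1, and 1.03, 0, 0.591, 0.510 and 0.951 for PCNA. In section 1, PCNA read 15.6, 0, 18.5, 20.4 and 17.7, the 0 coming from the shallow replicate 2. RNRS2 (GRMZM2G155546) fell by 1.21 and lost its call under quantile normalization (-0.39) and upper quartile scaling (-0.59) and with a pseudocount of 0.1 (adjusted p = 0.0609). Of 10 histones 9 fell and 1 rose (adjusted p = 0.00164, and adjusted p = 0.0568 with an estimated correlation). Among those that fell, his2b5 (GRMZM2G342515) went from 256 ± 8.4 to 7.26 ± 5.6 FPKM. The member that rose, named after its values were seen, was Hist1h3b, by 2.29 (adjusted p = 0.0429). Its call was lost with no filter on low values (0.0653), without the shallow libraries (0.192) and without replicate 2, 4 or 6 (0.319, 0.102 and 0.0719). In his2a1 (GRMZM2G305046), which fell by 4.37, section 9 read 3.38, 0, 2.89, 0 and 5.01 FPKM against 44.4 to 63.9 in section 1.

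Of 28 ribosomal proteins 23 fell and 1 rose (median -3.09, or -2.55 against all genes, adjusted p = 6.28e-05, and adjusted p = 0.268 with an estimated correlation). RPL27A (GRMZM2G047732) went from 846 ± 105 to 50.7 ± 27.9 FPKM, arpp2a (GRMZM2G119809) fell by 3.95 and RPS27A (GRMZM2G431821) by 3.88, whereas rpl19 (GRMZM2G171444) rose from 177 ± 29.5 to 454 ± 34.7. After quantile normalization or upper quartile scaling, 3 ribosomal protein genes rose. Of 24 stress and wounding genes 16 fell and 2 rose (median -2.99, adjusted p = 3.49e-05, and adjusted p = 0.222 with an estimated correlation). Those that fell included lipoxygenase and allene oxide synthase genes of jasmonate synthesis, lox1 (GRMZM2G156861) from 151 ± 17.8 to 4.62 ± 5.0 FPKM and aos1 (GRMZM2G067225) from 197 ± 38.4 to 5.97 ± 4.61, and the heat shock gene hsp22 (GRMZM2G007729) from 2574 ± 144 to 299 ± 87.6. For hsp3 (GRMZM6G199466), section 9 read 1.41 in replicate 1 and 0 in the other 4 libraries, against 18.4 to 58.2 in section 1. The 2 that rose, named after their values were seen, were the lipoxygenases lox10 by 1.56 and LOX8 by 1.21, and the call of LOX8 was lost with a pseudocount of 0.1 (adjusted p = 0.0815).

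Among regulators of leaf greening and patterning, G2-like1 (GRMZM2G026833, listed as GLK1), a regulator of chloroplast development, rose from 19.8 ± 2.8 to 136.5 ± 9.2 FPKM. SCR (GRMZM2G131516) fell from 33.2 ± 7.9 to 8.32 ± 3.05 and GRMZM2G132794, listed as SHR1, from 10.1 ± 1.18 to 1.10 ± 0.45 FPKM. GLK13 (GRMZM2G087804, listed as G2) stood at 12.1 ± 3.7 and 19.9 ± 4.7 FPKM and did not pass (adjusted p = 0.246), but passed after quantile normalization (0.000318) and rose by 1.38 after upper quartile scaling. Their list was not called (adjusted p = 0.702). Of the meristem KNOX genes only 2 were tested. Of these knox6 (GRMZM2G370332) read 3.80, 0, 6.52, 4.10 and 4.94 FPKM in section 1 and 5.99 to 9.68 in section 9. It rose by 1.21 (adjusted p = 0.0209), but by 0.71 without the shallow libraries, which ended the call, and the adjusted p was 0.247 without replicate 2, 0.0546 without replicate 4 and 0.0651 when only these 2 sections were fitted. For knox7 (GRMZM2G433591) the log2 change was -0.77 ± 0.33.

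Of the lists not called, some held members that went both ways. In sucrose and starch 5 of 12 rose and 4 fell (adjusted p = 0.486), in wall loosening 3 of 12 rose and 5 fell (0.885), in epidermal wax 2 of 6 rose and 3 fell (0.702), and in secondary wall and lignin 1 of 13 rose and 4 fell (0.892). Of 9 primary wall genes 6 fell (0.275), or 3 after upper quartile scaling, and of 3 mitosis genes mad2 fell (0.605), again named after its values were seen. The call of mad2 was lost with a pseudocount of 0.1 (adjusted p = 0.0547). With no filter on low values, 6 of 9 mitosis genes fell (adjusted p = 1.91e-06). Neither of the 2 chlorophyll breakdown genes nor the 1 clock gene passed, although all rose after upper quartile scaling. The median of the regulator, wax and sucrose and starch lists was negative (-0.61, -0.54 and -0.56) while their test pointed up, and after quantile normalization these medians were 0.07, 0.04 and 0.14. Adjusted over the list alone, the counts of every list fixed before were those given here.

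The 5 named genes that rose most were ME1, cab48, sog0622b (GRMZM2G014695, 3.55 ± 1.92 to 459 ± 43 FPKM), CYPPDKZM2 (GRMZM2G097457, 4.71 ± 1.40 to 407 ± 56.5) and PER42 (GRMZM2G126261, by 6.18). CYPPDKZM2 is a second pyruvate phosphate dikinase gene, and reads from similar copies may be counted for either. For PER42 section 1 read 2.25, 0, 2.34, 1.45 and 3.83 FPKM and section 9 from 169.8 to 213.6. Those that fell most were H4C13, ss2 (GRMZM2G152908), held in the sucrose and starch list as sus1, from 3899 ± 137 to 90.7 ± 125 FPKM, DWF1 (GRMZM2G057000) from 431 ± 19.7 to 8.98 ± 12.8, LTP3 (GRMZM2G126397) and DEF1 (GRMZM2G153488). LTP3 read 900 to 1311 FPKM in section 1 and 77.5, 8.62, 12.2, 0 and 16.4 in section 9. DEF1 read 450.9 to 543.8 and then 31.1, 2.08, 5.92, 0 and 4.76.

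In all, 11463 of 23055 maize genes changed between sections 1 and 9, of which 3460 rose (30.2%) and 8003 fell. The share that rose was 49.2% after quantile normalization and 48.4% after upper quartile scaling. The median change of all genes was -0.54 as given and -0.004 after quantile normalization. As many lists as the 10 called here were called in 31 of 100 ways of splitting the same 10 libraries, the labelled one included. Some other splits keep part of the difference between the sections, with up to 7696 genes called. The number of lists therefore cannot tell chance from a difference between the sections.

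From section 9 to section 16 of the maize leaf, 7 of 24 stress and wounding genes rose, among them genes of heat shock proteins, and none of the 17 C4 cycle genes passed. The call of the stress list was lost with an estimated correlation (adjusted p = 0.103). The chaperone gene hsp82 (GRMZM5G833699) went from 3.15 ± 1.88 to 57.8 ± 15.1 FPKM (SD, n = 5), a log2 change of 3.89 ± 0.41 (SE, limma adjusted p = 1.34e-10). In the same way hsp101 (GRMZM2G360681) rose from 28.6 ± 4.5 to 239.5 ± 64.0 FPKM and Hsp70 (GRMZM2G310431) from 144 ± 38.6 to 924 ± 298. The iron-phytosiderophore transporter gene ys1 (GRMZM2G156599) fell from 28.2 ± 9.9 to 2.18 ± 1.08 FPKM, by 3.19 ± 0.44. The light-harvesting gene cab-m9 (GRMZM2G155216) fell from 5828 ± 719 to 2536 ± 972 FPKM.

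Of 24 stress and wounding genes 7 rose and none fell (median 0.83, camera adjusted p = 2.80e-11, and adjusted p = 0.103 with an estimated correlation). Adjusted over the list alone, 10 rose, and the count was 11 without the libraries out of place and 6 after quantile normalization. HSP90-1 (0.88) and lox6 (0.95), named after their values were seen, were under the size threshold after quantile normalization, and hsp26 did not pass with a pseudocount of 0.1 (adjusted p = 0.0653). The member with the highest mean, hsp22, changed by 0.93 ± 0.18, under the size threshold, and passed at 1.13 without replicate 1, 1.01 without replicate 3 and 1.03 without the libraries out of place. In the light-harvesting list cab-m9 fell and the other 6 did not pass, Cab-m7 among them at -0.25 ± 0.14 (list adjusted p = 0.000203, and adjusted p = 0.209 with an estimated correlation), while 2 fell adjusted over the list alone or without the shallow libraries and 3 after quantile normalization. In the epidermal wax list CER1 (GRMZM2G099097), of alkane synthesis, was the 1 of 6 that fell. It read 4.97 to 8.90 FPKM in section 9, 0.643 in section 16 replicate 3 and 0 in the other 4 libraries of section 16. The most abundant member, gl1 (GRMZM2G114642), changed by -0.49 ± 0.40 (list adjusted p = 0.00100, and adjusted p = 0.103 with an estimated correlation).

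The primary wall and wall loosening lists were called as lower on few members, and both calls were lost with an estimated correlation (adjusted p = 0.161 and 0.105). Of 9 primary wall genes 1 fell, CesA-6 (GRMZM2G113137), a cellulose synthase, from 30.5 ± 2.7 to 15.1 ± 7.2 FPKM (adjusted p = 0.0268). The most abundant, CesA-7 (GRMZM2G025231), changed by -1.34 ± 0.58 and did not pass (0.174). It passed after quantile normalization (0.00861), after upper quartile scaling (2.25e-05), when only these 2 sections were fitted (0.0228) and without the shallow libraries (1.18e-05). The list adjusted p was 1.11e-05. Adjusted over the list alone, 6 fell, and 6 fell after quantile normalization and 7 without the shallow libraries. Of 12 wall loosening genes 2 fell, xth1 (GRMZM2G119783) from 48.2 ± 9.7 to 12.9 ± 10.4 FPKM and the expansin EXPA5 (GRMZM2G361064) from 9.98 ± 2.25 to 3.47 ± 2.59 (list adjusted p = 1.11e-05), while 6 fell adjusted over the list alone or after quantile normalization and 7 without the shallow libraries. The calls of CesA-6, xth1 and EXPA5 were lost with a pseudocount of 0.1 (adjusted p = 0.0526, 0.153 and 0.210). They were also lost when single replicates were left out. For CesA-6 the adjusted p was 0.160 without replicate 1 and 0.105 without replicate 4. For xth1 it lay from 0.0650 to 0.185 without replicate 1, 3, 4 or 6, and for EXPA5 from 0.103 to 0.147 without replicate 2, 3 or 4.

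None of the 17 C4 genes passed between sections 9 and 16 (limma, list adjusted p = 0.760). Mean FPKM stood at 2108 ± 146 and 2125 ± 794 for pep1, 2833 ± 209 and 3504 ± 1377 for ME1, and 15206 ± 913 and 18948 ± 7223 for C4ppdkZm1. Their log2 changes were -0.05 ± 0.29, 0.24 ± 0.38 and 0.25 ± 0.29. The section 16 means and SDs are raised by replicate 6, whose values ran high. It read 3539, 5941 and 31695 FPKM for these genes. The other 4 libraries read 1673 to 1868 for pep1, 2576 to 3077 for ME1 and 14353 to 17615 for C4ppdkZm1. The remaining C4 members lay between -0.71 ± 0.23 in pOMT1 (adjusted p = 0.0562) and 1.30 ± 0.79 in GRMZM2G001696, listed as PEP carboxykinase (0.396). When only these 2 sections were fitted, GRMZM2G001696 passed (adjusted p = 0.00697). The regulators did not pass either (list adjusted p = 0.141, or 0.0439 with no filter on low values). The log2 changes were 1.22 ± 0.49 in GLK13 (adjusted p = 0.141), 0.49 ± 0.21 in G2-like1, 0.60 ± 0.31 in GRMZM2G132794 and 0.21 ± 0.43 in SCR. GLK13 passed without the shallow libraries (9.46e-05), after upper quartile scaling (0.00798) and when only these 2 sections were fitted (0.0458), and, adjusted over the list alone, 1 of the 4 rose. The KNOX genes knox6 and knox7 changed by 0.03 ± 0.46 and 0.38 ± 0.33.

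The other lists were not called. In the Calvin-Benson cycle (adjusted p = 0.306) and bundle-sheath-preferred lists (0.473) the 1 member that rose was the activase RA, by 1.05, and none of either list rose after quantile normalization or upper quartile scaling or without replicate 6. The mesophyll-preferred list had none (0.306, or 0.0275 without replicate 6), nor had photosystem subunits (0.776), histones (0.307), DNA replication (0.948), mitosis (0.577) and secondary wall genes (0.306). Named after their values were seen, as RA was, sus2 rose in sucrose and starch (0.811) and SGR2 rose among 2 chlorophyll breakdown genes. Both calls were lost with a pseudocount of 0.1 (adjusted p = 0.336 and 0.213) and when single replicates were left out. For sus2 the adjusted p was 0.0528 without replicate 3 and 0.0554 without replicate 6. For SGR2 it lay from 0.0736 to 0.169 without replicate 1, 2, 4 or 6, and at 0.0528 with no filter on low values. The list of 28 ribosomal proteins (0.137) passed after quantile normalization (0.0128), without section 16 replicate 6 (0.0181) and without shallow and out of place libraries (0.0436). The clock gene tested did not pass. Adjusted over the list alone, 2 Calvin-Benson genes rose and 1 mitosis gene fell, and the counts were 2 and 1 without the shallow libraries as well. The medians of the C4, photosystem and mitosis lists, 0.06, 0.03 and 0.23, were positive while their tests pointed down.

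Besides hsp82, hsp101 and pip2-5 (GRMZM2G178693, an aquaporin, 10.7 ± 3.5 to 77.2 ± 37.9 FPKM), the named genes that rose most were ERTC (GRMZM2G051135), from 7.71 ± 3.92 to 100.004 ± 24.9 FPKM, and CKX10 (GRMZM2G348452), named for cytokinin oxidase, from 77.0 ± 10.7 to 518 ± 172. Those that fell most, besides ys1, were znod1 (GRMZM2G052562) from 72.1 ± 5.9 to 11.8 ± 9.2, -Mlo1 (GRMZM2G032219) from 24.5 ± 4.4 to 4.32 ± 3.90, LIM12 (GRMZM2G175761) and CNR7 (GRMZM2G119755). The call of znod1 was lost without replicate 1 (adjusted p = 0.0573). LIM12 read 5.77 to 17.7 FPKM in section 9 and 0, 0, 3.58, 1.40 and 0 in section 16, and CNR7 read 6.97 to 13.1 and then 0.863, 0, 0.713, 1.81 and 0.

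Between sections 9 and 16, 1204 maize genes changed, 876 up (72.8%) and 328 down. The share that rose was 49.2% after quantile normalization and 45.6% after upper quartile scaling. The count depended on the libraries fitted. It was 2795 without the shallow libraries, with all 1204 among them, 2462 without section 7 and 607 with a pseudocount of 0.1. Without section 16 replicate 6, whose values ran high, 511 rose and 301 fell. At least 5 lists were called in 19 of 100 splits of the same 10 libraries, the labelled one included.

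In rice, genes of walls were highest in the first sections and genes of carbon fixation and photorespiration, the salvage of the product of Rubisco's reaction with oxygen, in the later ones. On the log2(FPKM + 1) scale the primary wall genes averaged 7.15 ± 0.30 in section 1, 4.71 ± 0.23 in section 6 and 3.58 ± 0.73 in section 11 (SD, n = 4). Calvin-Benson genes averaged 8.61 ± 0.30, 12.27 ± 0.05 and 11.97 ± 0.43. Chlorophyll synthesis genes were highest in section 3, at 8.15 ± 0.19. The centre of mass lay at 27.1 ± 0.87% of the series for sucrose and starch genes, 29.0 ± 1.4% for primary wall, 29.7 ± 1.1% for secondary wall and 41.1 ± 1.6% for chlorophyll synthesis. Of the 4 sucrose and starch genes 2 rose and 2 fell from section 1 to section 6, so that position does not stand for each member. Light-harvesting genes lay at 54.4 ± 0.74%, photosystem subunits at 56.9 ± 0.39%, chlorophyll breakdown at 60.02 ± 3.67% and Calvin-Benson genes at 61.2 ± 0.46%. The C4 list, whose members are orthologues or relatives of the maize enzymes, lay at 61.4 ± 1.2%, photorespiration at 61.6 ± 0.54% and clock genes at 65.6 ± 2.1%. This order also rested on the measure. On linear FPKM chlorophyll synthesis lay at 59.1 ± 2.8%, after light-harvesting (54.8 ± 1.4%) and photosystem genes (57.7 ± 0.95%). The crossing of the middle of the range lay at 47.5 ± 5% for secondary wall genes, 22.5 ± 5% for the C4 list and 27.5 ± 5% for Calvin-Benson genes. As in maize, it marks the end of a high stretch in falling lists and the start of a rise in rising ones. These values therefore give no order between such lists.

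Of 17353 rice genes tested, 11921 differed among the 11 sections (limma F-test). For 4147 of them (34.8%) the highest section mean was in section 1, for 1676 in section 2, for 1074 in section 10 and for 700 in section 11. The largest step between neighbours was from section 1 to section 2, with 1 minus Pearson r at 0.157 ± 0.014 (SD, n = 4). The other steps lay between 0.0808 and 0.108. As the tables of the 2 species were normalized separately, no test was made between them.

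From section 1 to section 6 of the rice leaf, photosynthesis and photorespiration genes rose and cellulose synthase genes fell. LOC_Os01g45274, listed as carbonic anhydrase, went from 123 ± 70.8 to 17435 ± 3519 FPKM (SD, n = 4), a log2 change of 7.32 ± 0.35 (SE, limma adjusted p = 1.32e-19). LOC_Os03g03910, listed as catalase, which removes the hydrogen peroxide of photorespiration, rose from 24.4 ± 18.8 to 1141 ± 390 FPKM, by 5.77 ± 0.40. LOC_Os03g62090, listed as the cellulose synthase CESA5, fell from 63.9 ± 10.5 to 5.62 ± 0.56 FPKM, by 3.28 ± 0.35. LOC_Os10g32980, listed as CESA7 of secondary walls, fell from 68.7 ± 22.2 to 8.95 ± 2.53 FPKM, by 2.79 ± 0.36.

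All 14 Calvin-Benson genes rose (median 3.58, or 3.80 above all genes, camera adjusted p = 5.06e-17), as did all 13 photorespiration genes (median 3.98, adjusted p = 8.38e-17). All 12 light-harvesting genes rose with a median of 2.47 (adjusted p = 1.00e-09), and all 11 photosystem genes with a median of 2.40 (9.37e-11). After quantile normalization 3 light-harvesting genes rose with a median of 0.59 over the list, 3 that had risen stood at -0.44, -0.50 and -0.66 without passing, and the list was not called (adjusted p = 0.166), and 4 photosystem genes rose with a median of 0.69 (0.0150). Of 8 members of the C4 list 5 rose and 1 fell (adjusted p = 0.000703), the last a gene listed as PEP carboxylase. Of 5 clock genes 3 rose, those listed as LHY, PRR73 and PRR95 (adjusted p = 0.000833), and all 5 rose after quantile normalization. The calls of these 6 lists held with an estimated correlation, with adjusted p from 0.00350 for photorespiration to 0.0368 for clock and light-harvesting genes.

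Of 12 chlorophyll synthesis genes 5 rose and 2 fell (adjusted p = 0.0168, adjusted p = 0.257 with an estimated correlation, and 0.223 after quantile normalization). Those that fell were listed as CHLG and GSA, and GSA changed by -0.94 after upper quartile scaling, under the size threshold. All 5 primary wall genes fell (median -2.45, adjusted p = 0.00203, and adjusted p = 0.136 with an estimated correlation). Of 10 secondary wall and lignin genes 8 fell (adjusted p = 0.0246, and adjusted p = 0.347 with an estimated correlation). Without replicate 1 the secondary wall list was not called (0.0774). In lists not called or with under 3 tested members, chlorophyll breakdown had 1 of 4 that rose, listed as PAO (0.255), and sucrose and starch 2 that rose, SPS1 and SUT1, and 2 that fell, SUS1 and SUS2 (0.865). Of the 2 regulators tested GLK1 rose. The DNA replication gene tested, PCNA, fell, and the mitosis gene tested did not pass. With no filter on low values 8 of 9 DNA replication genes and 4 of 5 mitosis genes fell. No KNOX gene was tested. The members named in this paragraph were chosen after their values were seen, and adjusted over the list alone, every count was as given.

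In total 7944 rice genes changed from section 1 to section 6, with 3022 up (38.0%) and 4922 down. The share that rose was 50.1% after quantile normalization and 47.1% after upper quartile scaling, and the median change of all genes moved from -0.22 to 0.10 and 0. As many lists as the 9 called were called in 5 of the 35 splits of the same 8 libraries, the labelled one included.

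From section 6 to section 11 of the rice leaf, 9 of 10 secondary wall and lignin genes, 7 of 12 light-harvesting genes and 4 of 12 chlorophyll synthesis genes fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.0909 for each). LOC_Os01g52240, listed as the light-harvesting protein LHCB1, went from 12919 ± 2943 to 1264 ± 1053 FPKM (SD, n = 4), a log2 change of -3.63 ± 0.39 (SE, limma adjusted p = 3.63e-09). In section 11 replicate 2, which matched section 9 best, it read 2827 FPKM, against 629 to 948 in the other libraries of section 11. LOC_Os04g58200, listed as PORA, a reductase of chlorophyll synthesis, fell from 133 ± 52.2 to 6.10 ± 4.64 FPKM, by 4.35 ± 0.48. LOC_Os03g15050, listed as PEP carboxykinase, rose from 5.50 ± 2.16 to 53.1 ± 22.7 FPKM, by 2.98 ± 0.29. LOC_Os01g13740, listed as GLK2, rose from 23.3 ± 3.1 to 57.7 ± 12.2 FPKM, by 1.26 ± 0.19.

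Of 12 light-harvesting genes 7 fell (median -1.02, camera adjusted p = 4.17e-08), and of 11 photosystem genes 5 fell (median -0.98, adjusted p = 2.41e-06). Both had an adjusted p = 0.0909 with an estimated correlation. After quantile normalization 2 light-harvesting and no photosystem genes fell, with medians of -0.32 and -0.51, and without replicate 3 the light-harvesting count was 3. Of 12 chlorophyll synthesis genes 4 fell (adjusted p = 8.62e-05, and adjusted p = 0.0909 with an estimated correlation), listed as PORA, CHLD, CHLI and GSA. Of 10 secondary wall and lignin genes 9 fell with a median of -2.06 (adjusted p = 7.59e-09, and adjusted p = 0.0909 with an estimated correlation). Of 5 primary wall genes 4 fell, all but CESA5 (adjusted p = 0.00196, and adjusted p = 0.170 with an estimated correlation). When only these 2 sections were fitted, the calls of the members listed as CESA1, CESA3 and CESA8 were lost (adjusted p = 0.0545, 0.0849 and 0.0653). The call of CESA3 was also lost without replicate 1 (0.0559) and that of CESA8 without replicate 4 (-0.97). Adjusted over the list alone, 10 secondary wall genes fell and 1 photorespiration gene rose, with the other counts as over all genes.

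In the C4 list PEP carboxykinase was the 1 of 8 members that rose (adjusted p = 0.924), and of 14 Calvin-Benson genes 2 fell, both Rubisco small subunits (0.234). Neither passed after quantile normalization, when only these 2 sections were fitted (adjusted p = 0.477 and 0.245) or without replicate 3. Without replicate 3 they changed by -0.84 (adjusted p = 0.113) and -0.998 (0.0208), the second just under the size threshold. The first also did not pass without replicate 4 (0.0616) or with no filter on low values (0.0540). The Calvin-Benson list passed without replicate 2 (0.00598) and with sections 9 to 11 of replicate 2 left out (0.00606), and 4 members then fell. Photorespiration had 1 of 13 that fell, listed as glycine decarboxylase H (0.924), the clock list 1 of 5 that rose, GI (0.0751, or 0.0208 without replicate 1), and sucrose and starch 1 of 4 that fell, SUT1 (0.924), at -0.90 without replicate 1, with a median of 0.06 against a test that pointed down. Chlorophyll breakdown had PAO up and NOL down among 4 (0.725). The DNA replication and mitosis genes tested did not pass. Members other than PEP carboxykinase, PORA, GLK2 and the LHCB1 above were named after their values were seen.

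Between sections 6 and 11, 2918 rice genes changed, 1103 up (37.8%) and 1815 down. At least 5 lists were called in 12 of the 35 splits of the same 8 libraries, the labelled one included.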

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

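The fits that leave out shallow or out of place libraries, the low-depth test and the test of a one-way shift were chosen only after the results were seen.

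In 59 of 280 groups of 4 or 5 values (21.1%), 1 value lay far from the others by Dixon's criterion, where chance picks about 1 in 20 groups. Most came from a few libraries. In maize section 16, replicate 6 stood above the other 4 libraries in 21 groups. In FPKM it read 3539 for pep1, 11000.2 for GRMZM2G121878, 2439 for GRMZM2G348512, 1194 for GRMZM2G094165, 897 for mdh6, 5941 for ME1, 31695 for C4ppdkZm1, 5280.45 for GRMZM2G001696 and 48.5 for alt. It read 98.6 for pDCT1, 486 for pDCT2, 1942 for GRMZM2G138258, 782 for GRMZM2G174107, 1229 for GRMZM2G070605, 103 for GLK13, 319 for G2-like1, 6.09 for GRMZM2G132794 and 21.2 for knox6. It also read 12046 for Cab-m7, 2405 for PIP1-1 and 962 for hsp22. In the same section replicate 3 stood high at 0.643 FPKM for CER1 and 68.5 for CesA-7, and replicate 2 at 4.09 for YAB5.

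In maize section 9, replicate 1 stood apart in 10 groups, low at 1163 FPKM for GRMZM2G001696 and 1814 for RA, and high at 107 for H4C13, 1.41 for hsp3, 13.8 for aos1, 452 for hsp22, 77.5 for LTP3, 31.1 for DEF1, 309.7 for ss2 and 31.5 for DWF1. Replicate 3 of that section stood high at 28.0 for GLK13. In section 1 the shallow replicate 2 stood apart in 9 groups. It was high at 74.9 for mdh6 and 23.3 for GLN6, and low at 79.1 for pOMT1, 13.0 for pDCT1, 57.5 for GRMZM2G174107, 4.55 for knox7, 0 for PCNA, 68.7 for gln1 and 131 for aos1. Replicate 6 of section 1 was high at 146.6 for GRMZM2G121878, 64.8 for ME1 and 33.8 for GRMZM2G138258. In rice section 11, replicate 2 was high at 2827 for LOC_Os01g52240.

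Among distances between neighbouring sections, maize replicate 6 stood apart at 0.283 from section 2 to 3, 0.265 from 3 to 4 and, on the low side, 0.0850 from 4 to 6. Replicate 2 stood apart at 0.140 from section 10 to 11, 0.285 from 13 to 14 and 0.296 from 14 to 15. In rice, replicate 4 stood at 0.109 from section 7 to 8. Among positions along the maize leaf, replicate 6 was low for the Calvin-Benson cycle (56.8%) and the mesophyll-preferred genes (55.3%), and replicate 2 was high for wall loosening (42.6%). Replicate 4 was high for rice chlorophyll breakdown, at 65.5%.

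Maize section 16 against 9 called 2795 genes without the 6 shallow libraries and 1204 with them, although none of the 6 belongs to either section. Of 40 random sets of 6 other libraries left out, 0 reached 1.5 times the count, with the highest at 1512 genes and the median SD of a gene at 0.730 with all libraries and 0.478 without the shallow ones. A wider shared spread from the shallow libraries may therefore account for the lower count. Leaving out the libraries out of place gave 1713 genes, below 1.5 times the count. Section 16 replicate 3, from a compared section, is among those libraries, so that fit changed the section 16 mean as well as the spread. It therefore cannot decide whether the libraries out of place are the whole cause. No biological explanation was tested.

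Maize section 14 replicate 2 matched section 4 best, with r at 0.909 against 0.762 for its own section. Fitted as a mixture of section means, it took 25.9% from sections 12 to 16, which argues against a library of section 4 alone, and its relative depth of 1.15 argues against low depth. The share from sections 1 to 8 was 74.1%. It was 40.5% in section 15 replicate 4, the highest other library of sections 12 to 16 that was neither shallow nor out of place. A mixed sample of section 14 with an earlier section may account for the match. The library was flagged by that match to section 4, from which a high share of sections 1 to 8 largely follows. The share therefore adds little to it. The same fit gave 67.5% from sections 1 to 8 in section 12 replicate 4, 30.9% in section 14 replicate 3 and 28.8% in section 16 replicate 3. No biological explanation was tested.

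In rice replicate 2, sections 9 and 10 each matched the next section and section 11 an earlier one. The squared distance to the other replicates in the rotated order was 0.836 of that in the labelled order, and replicate 3 also preferred a swap of sections 10 and 11 at 0.996, so rotated labels cannot be told apart from spread between replicates that late in the leaf. Only 1 of the 3 matched an earlier section. Section 11 is the last and could not match a later one, so all 3 could not have matched later sections. Its match to section 9 (r at 0.940, against 0.923 for its own) is the pattern that raised the question. This test of sections displaced one way along the leaf therefore decides nothing beyond that pattern. No biological explanation was tested.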

How the results depend on the processing

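The fits without shallow, out of place or single other libraries were chosen only after the results were seen. Of 188 gene results, 176 to 188 kept their call under each planned setting fitted to all libraries. The exception was a mean FPKM of at least 5, where 177 were tested, all with the same call. A change of direction was counted only in genes called in at least 1 of the fits compared. The replicate block changed no call among the 188 gene and 68 list results and no count by over 1.5 times, with 11485 (11428 shared), 1268 (1197 shared) and 3110 genes (2918 shared) in maize 9 against 1 and 16 against 9 and in rice 11 against 6. After quantile normalization the rice photosystem gene listed as PSAK changed by -0.18 in section 6 against 1 and did not pass, nor did 3 light-harvesting genes (-0.44, -0.50 and -0.66), and the cause was not tested. With an estimated correlation 21 of 35 list calls were lost and 14 kept, and of the lists fixed before 0 were called in maize 16 against 9 and 0 in rice 11 against 6. With a mean of at least 5 fewer genes were tested (12127 and 10311), and 10493 maize genes differed among sections, 6690 changed in 9 against 1 and 729 in 16 against 9, with 7703 and 5186 in rice among sections and in 6 against 1. Maize 16 against 9 gave 607 genes with a pseudocount of 0.1 (551 shared), 1973 after upper quartile scaling (899 rose, 1074 fell, 1073 shared), 2795 without the shallow libraries, 2462 without section 7, 1713 without those out of place, and 3631 without shallow and out of place libraries (1200 shared). Upper quartile scaling left out section 7 replicates 2 and 4. Without section 16 replicate 6, 1543 maize genes had their highest mean in section 16. With single replicates left out, counts lay at 17338 to 18450, 10471 to 11295 and 836 to 1074 in maize, at 10835 to 11602, 7477 to 7834 and 2248 to 2892 in rice, and for lists at 10 to 10, 5 to 6, 8 to 9 and 5 to 6. The largest maize step began at section 7 with a pseudocount of 0.1 (0.461) and at section 8 without the shallow libraries (0.168). The spread of positions in maize was 75.7 by half-range crossing, which takes starts of rises and ends of high stretches alike. It was 51.4 on linear FPKM and 34.3 without the shallow libraries, where some replicates lacked sections. In rice it was 47.5 by half-range crossing and 48.1 on linear FPKM. The cause of these differences was not tested. In maize section 16 relative depth read 0.218 in replicate 2 and 0.109 in replicate 6, where high FPKM may lower the reading. Low depth limits the detection of changes in genes with low values. Genes listed at 0 there are not shown to be absent.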

Other observations

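Gene lists in this part, and the tests of direction and the splits for counts of genes, were chosen only after the results were seen.

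From section 1 to section 9, 5 of 8 tested genes of benzoxazinoid synthesis, a family of maize defence compounds, fell (camera adjusted p = 0.00888, and adjusted p = 0.199 with an estimated correlation). Of 9 genes of nitrate and ammonium assimilation 6 rose (adjusted p = 2.02e-05, and adjusted p = 0.125 with an estimated correlation). The indole-forming enzyme gene bx1 (GRMZM2G085381) went from 136 ± 6.77 to 6.81 ± 3.27 FPKM (SD, n = 5), bx2 (GRMZM2G085661) from 424 ± 44.7 to 27.6 ± 11.1, BX3 (GRMZM2G167549) from 787 ± 46.7 to 64.3 ± 22.7 and BX5 (GRMZM2G063756) from 903 ± 52.0 to 187 ± 16.1. GLN6 (GRMZM2G050514) rose from 13.2 ± 5.8 to 251 ± 29.5 FPKM and gln1 (GRMZM2G098290) from 79.6 ± 6.3 to 580.2 ± 69.7, and fgs1 (GRMZM2G036609) and gln2 (GRMZM2G024104) rose by 2.96 and 2.91. Of 10 tubulins 9 fell (adjusted p = 0.000388, and adjusted p = 0.199 with an estimated correlation), with tua4 (GRMZM2G152466) going from 2225 ± 149 to 238 ± 60.4 FPKM, while tub6 (GRMZM2G071790) fell by 5.39 and tub5 (GRMZM2G133802) fell by 4.54. TUB1 (GRMZM2G164696) read 13.95, 0, 4.16, 0 and 1.94 FPKM in section 9. Not called were other isoforms of C4 enzymes, with 1 up and 3 down of 7 (0.866), plasma membrane aquaporins, with 3 up and 1 down of 9 (0.445), and WOX and YABBY regulators, with 2 down of 4 (0.496, or 0.0159 with no filter on low values). The first pair had negative medians, -0.93 and -0.30, while their tests pointed up.

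From section 9 to section 16, genes of plasma membrane aquaporins, which pass water through cell membranes, rose in 4 of 9 cases (adjusted p = 2.24e-10, and adjusted p = 5.21e-05 with an estimated correlation). PIP2-6 (GRMZM2G047368) went from 127 ± 17.4 to 717 ± 293 FPKM (SD, n = 5), pip (GRMZM2G081843, listed as PIP1-5) from 106 ± 8.3 to 466 ± 122 and pip2-5 from 10.7 ± 3.5 to 77.2 ± 37.9, and the most abundant, PIP1-1 (GRMZM2G174807), changed by 0.89 ± 0.13, under the size threshold. In section 16 the values of replicate 6 ran high, at 2405 FPKM for PIP1-1 against 1217 to 1480 in the other libraries. After quantile normalization or upper quartile scaling, and with section 16 replicate 6 left out, 3 aquaporins rose, and pip2b (GRMZM2G092125), named after its values were seen, was then under the size threshold (0.77, 0.91 and 0.99). Of 10 tubulins 1 fell, TUBB2 (GRMZM2G334899), at 0.942, 0, 2.59, 0 and 1.77 FPKM in section 16 (list adjusted p = 6.46e-05, and adjusted p = 0.103 with an estimated correlation), while tua4 changed by -0.80 ± 0.40, or by -1.02 after upper quartile scaling, where it passed. After quantile normalization 4 tubulins fell, and without the shallow libraries 3. Of 4 WOX and YABBY regulators YAB5 (GRMZM2G116646) fell, at 0.394, 4.09, 1.10, 0.782 and 0 FPKM in section 16 (list adjusted p = 0.00737, and adjusted p = 0.0605 with an estimated correlation), and YAB11 (GRMZM2G141955) changed by -1.13 ± 0.42 and did not pass, but passed after quantile normalization (0.00235), after upper quartile scaling (0.0122) and without the shallow libraries (0.000266). The calls of TUBB2 and YAB5 were lost with a pseudocount of 0.1 (adjusted p = 0.0624 and 0.0987) and when only these 2 sections were fitted (0.125 and 0.136). That of TUBB2 was also lost with no filter on low values (0.0660) and without replicate 2, 3, 4 or 6 (0.0647 to 0.193), and that of YAB5 without replicate 3 (0.0820), without replicate 6 (0.220) and without section 16 replicate 6 (0.0930). Not called were nitrate and ammonium assimilation, with 1 up and 1 down (0.257, or 0.0404 after quantile normalization), benzoxazinoid synthesis, with bx1 up (0.909), a call lost without any 1 replicate (adjusted p from 0.0594 to 0.108), and other isoforms of C4 enzymes, with 1 up (0.257).

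The labels leave the direction of the section numbers open. Grass leaves grow from a division zone at the base, so a hypothesis is that section 1 may lie nearest the base. Among the members of the DNA replication, mitosis and histone lists past the test in maize section 9 against 1, 14 fell and 1 rose, and in rice section 6 against 1, 12 fell and 0 rose with no filter on low values, which is consistent with that hypothesis and was tested on the data that raised it.

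Other splits of the same libraries into groups of the same sizes gave fewer changed genes than the labelled one in each comparison. The labelled one was the 1 split that reached its count. These splits ignore the pairing by replicate number, so they do not exclude chance for samples of the same pooled plants. Out of 100 splits the highest other was 7696 against 11463 in maize 9 against 1, 269 against 1204 in 16 against 9 and 2727 against 19049 among sections. Out of 35 splits it was 3474 against 7944 in rice 6 against 1 and 1126 against 2918 in 11 against 6, and out of 100 it was 315 against 11921 among rice sections. Chance cannot be excluded for the numbers of called lists, and these splits cannot decide it, as some keep part of the difference between the sections. With the labelled split included, as many lists were called in 31 of 100 splits in maize 9 against 1 (10, highest other 10), 19 of 100 in 16 against 9 (5 and 9), 5 of 35 in rice 6 against 1 (9 and 9) and 12 of 35 in 11 against 6 (5 and 7). Splits that part every pair of replicates, the labelled one included, numbered 14 of 100 in maize and 8 of 35 in rice, too few for a share under 0.05, with highest other counts of 6665 and 63 genes in maize and 2481 and 607 in rice.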
